A study of Mus musculus with 4 samples.

How the data were processed

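The samples are single-cell RNA libraries from the esophagus of 10 mice in a model of eosinophilic esophagitis, an allergic inflammation of the esophagus. Per the labels' protocols, live CD45+ (immune) cells of 5 wild-type and 5 Il20rb knock-out animals were tagged with 1 hashtag antibody per animal, pooled, sorted, and loaded on 2 wells of a droplet instrument for 3′ end libraries with molecular identifiers (UMIs). The GEO samples are 2 RNA libraries and 2 hashtag libraries, 1 of each per well, so the animal, known from its hashtag, was taken as the replicate. Hashtags B0301 to B0305 mark wild-type animals and B0306 to B0310 knock-out animals, numbered 1 to 5 within each genotype in that order.

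The authors deposited 1 table of UMI counts per gene and cell, with no normalization, covering 32285 genes and 6054 cells; its cell names give well, genotype and hashtag, per the file headers. Per the submitters' processing notes, Cell Ranger 6.0.1, R 4.0.5 and the mouse build mm10 were used, without their roles. The hashtag calling method, the annotation release and whether counting used strand are not given in the sources used here. Every cell in the table held between 1000 and 52182 UMIs, at least 501 genes and at most 9.99% mitochondrial UMIs, so cells had already been filtered before deposit. The protocol aimed at 10000 cells per well, and the table holds 2885 cells of well 1 and 3169 of well 2. Hashtag counts were not used here: cells were assigned to animals by the authors' calls, and in 0 of the cells did the genotype in the name differ from the one that the deposited hashtag table and the labels give its hashtag. Gene symbols came from a reference table of gene names for build GRCm38.p6, the patch release of mm10, which also gave coordinates; 32158 of the gene identifiers matched a symbol, 127 did not, and 52 that shared a symbol were kept as identifiers.

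No cell was removed. Scrublet, run in scanpy 1.11.5 for each well, called 3 cells (0.0496%) doublets, which is too few to count as a working call, so only an alternative without the top 5% of scores was run. Counts were scaled per cell, logged, reduced to 2000 variable genes and 30 principal components, and clustered by Leiden (igraph 0.11.9, 15 neighbours, resolution 3) into 63 clusters, after 6 clusters that also raised markers of another type were split further. Clusters were named from 212 markers of 27 cell types: at least 3 markers of the type raised by 1 log2 unit over all other cells, and leading genes that did not speak for another type. The names are rebuilt and not the authors', so each class is "X-like". The 5 clusters that met no rule stayed unnamed and held 12.7% of wild-type and 17.2% of knock-out cells, as means over animals. Cluster folds had 20 CPM added.

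For each animal, UMI counts were summed over all its cells and over each class with 10 or more cells in that animal; a class was tested with 3 or more such animals per genotype. Sums of all CD45+ cells and of 7 classes were tested by edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and the robust quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM after TMM scaling unless they are raw CPM of all cells. All fold changes are log2, knock-out over wild type, with standard errors. UMIs per animal ranged from 1805883 to 5666994; in the tested classes the sums ranged down to 34483 UMIs, in T-like cells. Shares of cells per animal and levels of single genes were compared by two-sided exact permutation tests over all 252 ways to split 10 animals 5 against 5, whose smallest p is 0.00794; 95% intervals of single shares are exact binomial ones and cover counting error only.

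Gene lists, 29 in all, were tested in each class with 3 or more measured members by camera in limma 3.58.1 with a preset correlation of 0.01 on log CPM (prior count 2), with Benjamini-Hochberg adjustment over 104 pairs of list and class. The camera test with an estimated correlation and fry were alternatives. Differences of the genotype effect between classes were tested in edgeR as an interaction of class and genotype, with the animal as a term, between the 2 most abundant lymphoid classes (ILC2-like, T-like) and the 2 most abundant myeloid ones (monocyte-like, cDC2-like). The code was tested on simulated counts with the mean profile of the real data: 60.6% of genes changed 2-fold and 93.8% of those changed 4-fold were recovered in all CD45+ cells, 45.5% and 96.8% in cycling cells, and 70.1% and 100% in monocyte-like cells. The interaction test between ILC2-like and monocyte-like cells recovered 33% and 89%. A list raised 2-fold in simulated monocyte-like counts was recovered, with 0 of the unchanged lists past the threshold. Genes were drawn independently there, so this cannot show false calls of lists whose members vary together. In the real monocyte-like cells the estimated correlation was 0.862 for the type I interferon list and 0.68 for the MHC class I list.

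The grouping, tests, markers, lists, alternatives and the rule for named genes were fixed before the data were examined. Named are up to 10 genes higher and up to 10 lower with the smallest adjusted p among those called; where fewer than 5 are called, the 5 smallest p on each side; the IL-20 receptor family and type 2 cytokine genes; and 2 to 4 members of each list past its threshold. A few genes that this rule names are not reported here. Ribosomal protein, mitochondrial, immunoglobulin variable and T cell receptor variable genes are counted but not named unless fewer than 5 genes pass or, for mitochondrial genes, their own list passes; Rpl29 is named in monocyte-like and ILC2-like cells after its values were seen. Alternatives were DESeq2 1.42.0, other scalings, no filter on low counts, no robust dispersion, each well alone, each animal left out, at least 20 cells per animal, other cluster resolutions and the immune classes as denominator. Those without the top doublet scores, without monocyte-like and neutrophil-like cells, and the leave-one-out fits of the interaction were chosen after seeing the data, as were 2 lists of glucocorticoid-responsive genes used in the closing section. Left out of tests were the classes with too few animals, such as neutrophil-like and B-like cells, for which shares are given. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.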

Results

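IL20RB is a subunit shared by the receptors for IL-19, IL-20 and IL-24. The series compares esophageal immune cells of 5 wild-type and 5 Il20rb knock-out mice. Per the labels' protocols, all animals were sensitised through the ear with calcipotriol (MC903) and ovalbumin for 14 days, challenged with ovalbumin by drinking water and by gavage on days 15 and 17, and sampled on day 18. No unchallenged animals are among the samples, so the values compare genotypes within the model only. The table holds 3421 wild-type cells (684 ± 165 per animal, mean ± SD) and 2633 knock-out cells (527 ± 246), a difference within the spread between animals (exact permutation p = 0.262). The median depth per cell was 4776 ± 913 UMIs in wild-type and 5733 ± 379 in knock-out animals (exact permutation p = 0.0794).

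Il20rb itself was close to absent from these cells in both genotypes. It gave 16 UMIs in all, 10 in wild-type and 6 in knock-out animals, or 0.501 ± 0.390 against 0.402 ± 0.101 raw CPM (exact permutation p = 0.595, n = 5 per genotype). A level of 3 counts in an animal corresponds to 0.529 to 1.66 CPM. Reads of the 3′ end can come from an allele that makes no protein, so the gene neither checks nor contradicts the genotypes. Il20ra, its partner chain, gave 1 UMI, the ligand Il19 gave 4, and Il20, Il24, Il22 and Il22ra1 gave 0. Il10rb, a chain of the receptors for IL-10 and IL-22, was measured in full and stood at 103 ± 37.0 and 92.7 ± 32.2 CPM (exact permutation p = 0.651).

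Group 2 innate lymphoid cells, early sources of IL-5 and IL-13, made up 6.83 ± 2.45% of wild-type and 2.73 ± 1.24% of knock-out cells (294 ILC2-like cells, exact permutation p = 0.0238, adjusted p = 0.270, n = 5 per genotype). T-like cells made up 5.23 ± 2.05% and 2.47 ± 1.47% (exact permutation p = 0.0556, adjusted p = 0.315). B-like cells made up 2.24 ± 3.18% and 0.356 ± 0.339% (exact permutation p = 0.0317, adjusted p = 0.270). In wild-type animal 3 they made up 7.91% of cells, and without that animal the means were 0.821% and 0.356% (exact permutation p = 0.0635, adjusted p = 0.432). Conventional type 2 dendritic cells (cDC2-like), which present antigen to helper T cells, held 15.4 ± 4.74% and 21.9 ± 9.29% (exact permutation p = 0.214). The cDC1-like cells held 2.87 ± 1.25% and 4.10 ± 2.07%, and macrophage-like cells 15.9 ± 6.51% and 15.7 ± 5.14%. Monocyte-like cells (19.0 ± 9.90% and 25.7 ± 22.1%) and neutrophil-like cells (11.9 ± 13.7% and 3.37 ± 3.90%) varied most. They ranged from 2.58% to 49.3% of monocyte-like cells among knock-out animals and from 1.61% to 35.1% of neutrophil-like cells among wild-type animals.

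None of the 17 classes passed the exact permutation test after adjustment (0 at adjusted p under 0.05, 2 at an unadjusted p under 0.05; edgeR on cell counts gave ILC2-like cells an adjusted p of 0.180). With monocyte-like and neutrophil-like cells taken out of the denominator, a choice made after seeing the data, 3 classes passed, each with the smallest p that the permutations can give (exact p = 0.00794, adjusted p = 0.0450). ILC2-like cells fell from 10.4 ± 3.25% to 3.91 ± 1.03% and T-like cells from 7.74 ± 1.98% to 3.42 ± 1.22%. The share of cDC2-like cells rose from 22.5 ± 2.90% to 30.3 ± 2.47%. Shares of 1 whole depend on each other, so these 3 results are not separate. A higher share does not show more cDC2-like cells in the tissue, and the table holds 504 in wild-type and 492 in knock-out animals. Unnamed cells made up 12.7 ± 3.75% of wild-type and 17.2 ± 5.27% of knock-out cells (exact permutation p = 0.167).

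**Figure D1:**
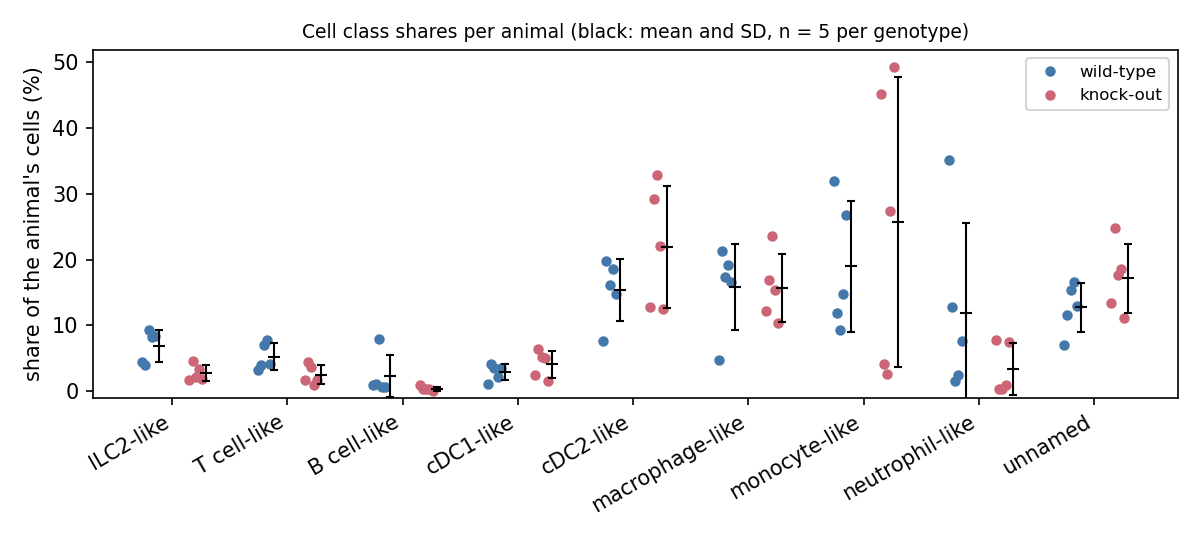
Share of an animal's cells (percent) in 9 classes, for wild-type and knock-out animals; each point is 1 animal and bars give mean ± SD, n = 5 per genotype. ILC2-like cells stood at 6.83% and 2.73%, while monocyte-like cells spread from 2.58% to 49.3% among knock-out animals.

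Eosinophils, the cells that name the disease, were the name of no cluster. The table holds no cell under 1000 UMIs or 501 genes, and median UMIs fell to 1251 in a neutrophil-like cluster. Granulocytes with fewer UMIs may therefore be missing, so low counts of eosinophil genes do not show that the tissue lacked eosinophils. Of their genes, Epx, Ear1 and Ear6 gave 0 UMIs, and Siglecf gave 75 (2.27 ± 1.18 against 1.82 ± 0.365 raw CPM, exact permutation p = 0.548). Prg2 gave 56, Alox15 gave 150 and Ear2, a ribonuclease, 2358 (81.4 ± 48.2 and 63.7 ± 32.7 CPM, exact permutation p = 0.524). In 3 clusters, 1 named cDC2-like and the others unnamed, eosinophil markers had the highest mean fold of any type, but none of these met the rule for the name. Ccr3, the eotaxin receptor, gave 23 UMIs and stood at 0.975 ± 0.475 and 0.162 ± 0.239 CPM (unadjusted exact permutation p = 0.0159). No animal gave more than 6 UMIs of it, and no knock-out animal more than 3. Il5ra, the IL-5 receptor, gave 29 UMIs in wild-type and 1 in knock-out animals, nearly all in wild-type animal 3. That animal also gave 50 of the 56 UMIs of Prg2 and held the largest shares of B-like (7.91%) and plasma-like cells (2.10%). Which cells carried these UMIs was not tested, so they do not show eosinophils there. The type 2 cytokine Il5 stood at 6.02 ± 1.36 and 2.79 ± 2.29 raw CPM of all cells (exact permutation p = 0.0317), but did not pass among all genes in edgeR (log2 fold -1.05 ± 0.38, adjusted p = 0.599). Il13 (10.4 ± 15.3 and 2.16 ± 2.28 CPM, exact permutation p = 0.206) and Il4 (20.5 ± 41.3 and 10.4 ± 22.5, exact permutation p = 0.492) rested on few cells and single animals. As shares of cells with a UMI, Il4 stood at 0.594 ± 0.351% and 0.148 ± 0.227% (unadjusted exact permutation p = 0.0476, 25 cells in all). Il13 stood at 0.642 ± 0.346% and 0.349 ± 0.224% (exact permutation p = 0.151). Il1rl1, the IL-33 receptor, stood at 69.6 ± 23.2 and 60.2 ± 34.2 (exact permutation p = 0.619).

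Over all CD45+ cells, 4 genes were lower in knock-out animals and 0 higher by edgeR, against 53 lower and 21 higher by DESeq2. The 4 edgeR calls come first. Rpl29, a protein of the large ribosomal subunit, fell from 1014 ± 69.4 to 568 ± 58.9 CPM (log2 fold -0.83 ± 0.09, adjusted p = 0.00711), with every knock-out animal below every wild-type animal. The transcript AC102496.1 fell from 51.7 ± 16.8 to 11.9 ± 2.55 CPM (-2.14 ± 0.23, adjusted p = 0.00711). Il7r, the IL-7 receptor of lymphoid cells, fell from 140 ± 12.5 to 83.7 ± 2.99 (-0.74 ± 0.08, adjusted p = 0.00946). The noncoding RNA Gm42031 fell from 116 ± 60.9 to 10.7 ± 4.58 (-3.48 ± 0.42, adjusted p = 0.0198). Among genes that did not pass, the nucleotide hydrolase Nudt16 (1.77), the extracellular superoxide dismutase Sod3 (1.72), Acvrl1 (0.71), BC028528 (0.62) and Stom (0.57) had positive log2 folds. Serpinb1a, an inhibitor of neutrophil proteases, had a negative one (-0.99). These 6 genes stood at adjusted p values of 0.0654 or above.

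By edgeR, 10175 genes were tested with 5 animals per genotype, and 697 had an unadjusted p under 0.05. DESeq2 called 74 genes, all 4 among them. Leaving out wild-type animal 4 left 2, leaving out knock-out animal 4 left 1, and well 1 alone gave 2. Without monocyte-like and neutrophil-like cells, chosen after seeing the data, 43 genes were called. Copies of Rpl29 elsewhere in the genome can share its reads, and the reference table gives no coordinates for AC102496.1.

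**Figure D2:**
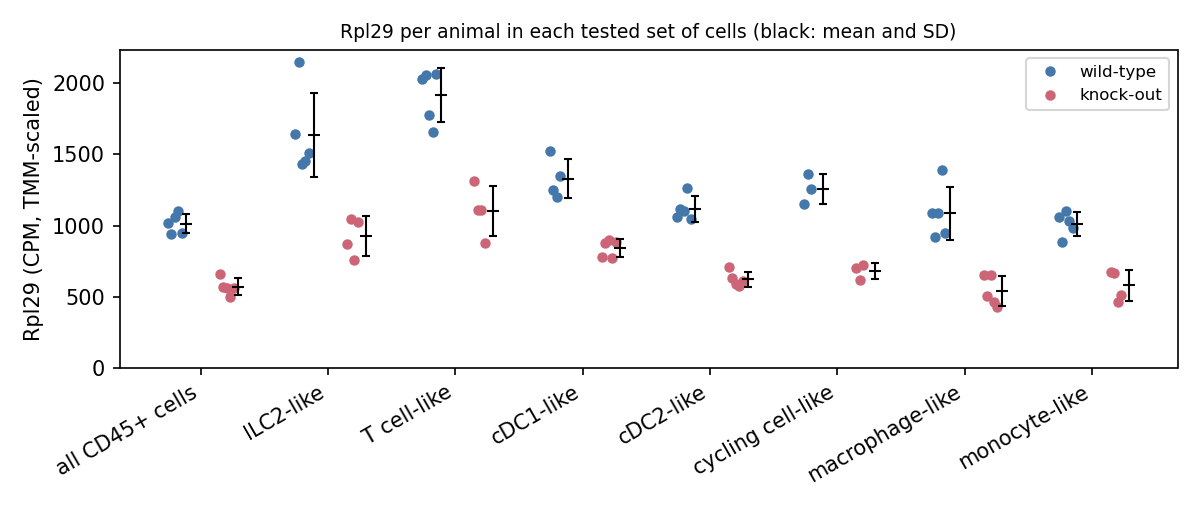
Rpl29 level (CPM after TMM scaling) in 8 sets of cells, by genotype; each point is 1 animal. Knock-out animals lay below wild-type animals in every set shown, from 941.9 CPM in the lowest wild-type against 661.3 in the highest knock-out animal over all CD45+ cells.

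In ILC2-like cells, 3 genes rose and 4 fell in knock-out animals. Lgals1, which encodes the lectin galectin-1, rose from 3057 ± 402 to 5205 ± 509 CPM (log2 fold 0.76 ± 0.14, adjusted p = 0.00185). Crip1 rose by 0.62 ± 0.13 (adjusted p = 0.0161) and Pxdc1 by 1.07 ± 0.24 (adjusted p = 0.0300). AC102496.1 fell from 499 ± 110 to 139 ± 68.7 CPM (-1.91 ± 0.29, adjusted p = 0.000223), and Rpl29 fell by 0.81 ± 0.17 (adjusted p = 0.0161). Txnip, an inhibitor of thioredoxin, fell from 827 ± 275 to 344 ± 108 (-1.24 ± 0.27, adjusted p = 0.0404). Ptafr, the receptor for platelet-activating factor, fell from 328 ± 111 to 112 ± 65.3 (-1.62 ± 0.38, adjusted p = 0.0495). Their hallmark genes did not pass: Il5 had a log2 fold of 0.41 ± 0.30 (adjusted p = 0.735) and Il1rl1 of -0.24 ± 0.19 (adjusted p = 0.777). The list of type 2 cytokines and receptors had 3 of 6 measured members higher (median log2 0.02, camera adjusted p = 0.867).

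The edgeR test held 1553 genes in 5 wild-type and 4 knock-out animals (DESeq2 called 6, 5 of them shared), and Lgals1 and Txnip overlap other genes. Leaving out 1 animal gave 2 to 10 genes, with 4 without wild-type animal 4, 3 without wild-type animal 5 and 2 without knock-out animal 1.

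In T-like cells no gene passed. The lowest p values belonged to Zfp36l2, an RNA-binding protein that destabilises transcripts (log2 fold -1.24 ± 0.25, adjusted p = 0.0626), and Rpl29 (-0.78 ± 0.16, adjusted p = 0.0626). Next came the glucocorticoid-induced Tsc22d3 (-1.74 ± 0.40, adjusted p = 0.128), Il7r (-0.92 ± 0.23, adjusted p = 0.160) and Capg (-1.04, adjusted p = 0.324). On the other side stood Rack1 (0.42), Arl4c (0.79), the integrin chain Itga4 (0.95), Sbno1 (0.99) and Sec61b (0.55), at adjusted p values from 0.341 to 0.449. The 4 measured genes of the type 17 and IL-22 program were all lower (median log2 -1.03, camera adjusted p = 0.0129, adjusted p = 0.674 with an estimated correlation), led by Tmem176b (-1.83), Tmem176a (-1.24) and the transcription factor Rora (-0.82). Of them, 0 passed over all genes in edgeR and 0 adjusted over the list alone. Pooled over animals, the T-like cluster led by Trdc and Cd163l1 held 35 of 174 wild-type and 5 of 57 knock-out T-like cells. The one led by Xcl1, Nkg7 and Ccl5 held 42 and 22. Both were picked after their counts were seen, and neither was tested. By edgeR, 0 of 1008 genes passed and 83 had an unadjusted p under 0.05 (5 against 4 animals; DESeq2 called 3). Leaving out knock-out animal 1 gave 2 genes, and wild-type animal 1 or 2 gave 1 each.

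In cDC1-like cells, which cross-present antigen, 3 genes fell and 1 rose. Rpl29 fell by 0.67 ± 0.13 log2 (adjusted p = 0.0261). The transcript Gm43305 fell from 103 ± 33.1 to 22.4 ± 11.7 CPM (-2.09 ± 0.42, adjusted p = 0.0294) and Tsc22d3 from 349 ± 147 to 154 ± 27.0 (-1.17 ± 0.25, adjusted p = 0.0356). Phf11a rose from 18.1 ± 13.3 to 103 ± 47.8 CPM (2.22 ± 0.46, adjusted p = 0.0356). Of 5 measured type I interferon response genes, 5 were higher (median log2 1.25, camera adjusted p = 0.00410, adjusted p = 0.850 with an estimated correlation), with 0 past the edgeR test over all genes and 1 adjusted over the list alone. Xaf1 stood at 1.25, Stat2 at 0.75 and Isg15 at 3.01 (adjusted p = 0.873). Of 10 MHC class I genes, 9 were higher (median 0.22, camera adjusted p = 0.0110, adjusted p = 0.674 with an estimated correlation), such as Psmb9 (0.46) and H2-T23 (0.49), with 0 past over all genes and 0 adjusted over the list alone. Others that did not pass were Limd1 (-1.34), the nucleolar protein Ncl (-0.69), Phf11b (0.94), Snx2 (1.11), Manf (0.75) and Lgals3 (0.44).

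These calls were fragile. Of 2010 genes tested by edgeR in 4 wild-type and 5 knock-out animals, 110 had an unadjusted p under 0.05. DESeq2 called 1 gene, and edgeR in the fit without robust dispersion and the one with at least 20 cells per animal called 0. Leaving out any single animal left 0 to 2. The count was 0 without wild-type animal 3, 4 or 5 or knock-out animal 4, 1 without wild-type animal 2 or knock-out animal 1, and 2 without knock-out animal 2, 3 or 5.

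In cDC2-like cells, Rpl29 fell from 1116 ± 88.1 to 621 ± 53.8 CPM (log2 fold -0.85 ± 0.09, adjusted p = 2.85e-05) and Ddit4, a stress-induced inhibitor of mTORC1, from 41.4 ± 4.98 to 15.7 ± 5.66 (-1.40 ± 0.24, adjusted p = 0.0322). In the chosen edgeR fit no gene rose, while DESeq2 called 2 genes higher and 6 lower. Short of the edgeR threshold were Gm43305 (-1.44) and Gm42031 (-2.87, both adjusted p = 0.0561), Gm14636 (1.21, adjusted p = 0.0584). So were Fkbp5, a glucocorticoid-induced immunophilin (-1.56, adjusted p = 0.0732), and the survival gene Bcl2a1a (0.68, adjusted p = 0.0732), as well as Mpp7 (1.26), Slc29a1 (0.99) and the TGF-beta receptor Tgfbr2 (1.00). Of 13 MHC class II genes, 10 were higher (median log2 0.19, camera adjusted p = 0.0213, adjusted p = 0.749 with an estimated correlation), with 0 past over all genes and 4 adjusted over the list alone. Among the leading ones were Cd74 (0.23), H2-Ab1 (0.23) and H2-Eb1 (0.24). Of 13 mitochondrially encoded genes, 1 was higher (median -0.11, camera adjusted p = 0.0393, adjusted p = 0.996 with an estimated correlation). The leading ones were mt-Nd5 at -0.26, mt-Co3 at -0.17 and mt-Co1 at -0.14, and 0 passed over all genes and 0 adjusted over the list alone. The edgeR test held 5941 genes in 5 animals per genotype, 288 with an unadjusted p under 0.05. DESeq2 called 8. Leaving out wild-type animal 1 or 3 gave 6 genes each and leaving out wild-type animal 2 or 4 or knock-out animal 2 or 4 gave 1 each.

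In cycling cells, Gm42031 fell from 273 ± 40.2 to 27.1 ± 9.68 CPM (log2 fold -3.21 ± 0.28, adjusted p = 9.73e-05) and Rpl29 by 0.89 ± 0.12 (adjusted p = 0.0119), with 0 genes higher. Of 18 cell cycle genes, 17 were higher (median log2 0.19, camera adjusted p = 0.00407, adjusted p = 0.850 with an estimated correlation), such as Ccnb2 (0.50), Pcna (0.43) and Rrm2 (0.48). Of these genes, 0 passed over all genes and 0 adjusted over the list alone. Tsc22d3 (-1.03, adjusted p = 0.134), the syndecan Sdc4 (-2.23) and Ifi30 (-0.56) did not pass. On the other side, the fatty acid desaturase Scd2 (1.34) and cyclin Ccne2 (1.27) did not pass either. With 3 animals per genotype, edgeR tested 4656 genes, 178 of them with an unadjusted p under 0.05, and DESeq2 called 2. Leaving out wild-type animal 3 or 4 or knock-out animal 2 left 1.

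In macrophage-like cells, Nudt16 rose from 9.55 ± 5.78 to 51.3 ± 13.6 CPM (log2 fold 2.48 ± 0.37, adjusted p = 0.0117). Gm42031 fell by 3.19 ± 0.47 (adjusted p = 0.0117) and Rpl29 from 1086 ± 188 to 539 ± 106 (-1.01 ± 0.17, adjusted p = 0.0378). The chemokine receptor Cxcr4 (-1.52, adjusted p = 0.0517), the lysosomal enzyme Glb1 (-1.42), the prostaglandin D synthase Hpgds (-1.44), Tuba1a (0.86), Adss (0.90), the interferon-induced GTPase Igtp (1.55) and Naaa (0.68) did not pass. Of 12 MHC class I genes, 12 were higher (median 0.52, camera adjusted p = 1.60e-06, adjusted p = 0.719 with an estimated correlation), for example H2-D1 (0.46), H2-T23 (0.61) and Tap2 (0.56). So were 17 of 17 type I interferon genes (median 0.98, camera adjusted p = 0.000503, adjusted p = 0.996 with an estimated correlation), for example Oas2 (1.13), Stat2 (0.84) and Oas3 (1.51). Of 10 MHC class II genes, 9 were higher (median 0.47, camera adjusted p = 0.0188, adjusted p = 0.996 with an estimated correlation), for example Ciita (0.77), Cd40 (0.69) and H2-DMa (0.55). Of 16 lipid and lysosome genes, 1 was higher (median -0.35, camera adjusted p = 0.00279, adjusted p = 0.850 with an estimated correlation), with Trem2 at -0.52, Abca1 at -0.31 and Ctsd at -0.61. Of 14 NF-kB targets and inflammatory cytokines, 4 were higher (median -0.24, camera adjusted p = 0.0456, adjusted p = 0.978 with an estimated correlation), with Cxcl1 at -1.31, Tnf at -0.83 and Ccl3 at -0.72. In each of these 5 lists, 0 genes passed over all genes and 0 adjusted over the list alone. Pooled over animals, the macrophage cluster led by Apoe, Gpnmb and Trem2 held 116 of 511 wild-type and 53 of 371 knock-out macrophage-like cells, while the one led by Spp1 held 119 and 106. At the doubled resolution, a cluster led by Ccl8 and Timp1 held 11 of 547 and 65 of 425. These clusters were picked after their counts were seen, and none was tested.

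By edgeR, 5299 genes were tested in 5 animals per genotype, 253 with an unadjusted p under 0.05. DESeq2 called 4, and each well alone 0. Leaving out wild-type animal 1 gave 5 genes, knock-out animal 1 gave 6, and wild-type animal 4 or knock-out animal 2 gave 1.

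Monocyte-like cells held the most calls, 31 genes higher and 11 lower in knock-out animals. Cd74, the MHC class II invariant chain, rose from 1224 ± 63.1 to 3448 ± 1340 CPM (log2 fold 1.50 ± 0.20, adjusted p = 0.0236) and H2-Ab1 from 219 ± 48.5 to 801 ± 371 (1.89 ± 0.29, adjusted p = 0.0267). The costimulatory receptor Cd40 rose by 1.27 ± 0.24 (adjusted p = 0.0295). The class I genes that rose were H2-T23 (1.14 ± 0.22, adjusted p = 0.0343), Tapbp (0.85 ± 0.17, adjusted p = 0.0365) and Psmb10 (0.75 ± 0.16, adjusted p = 0.0480). Other genes that rose were Ifi208 (4.82 ± 0.63, adjusted p = 0.0251, 23 against 945 UMIs), Gbp7 (1.30 ± 0.23, adjusted p = 0.0274), the GTPase Gbp5 (1.63 ± 0.31, adjusted p = 0.0353) and the proteasome activator Psme1 (0.94 ± 0.17, adjusted p = 0.0274). So did Tmsb10 (0.62), Rilpl1 (2.37), Cd180 (1.25), Fam111a (0.96) and Mapk9 (1.50). Lipoprotein lipase, Lpl, fell from 330 ± 117 to 89.0 ± 38.2 CPM (-2.10 ± 0.35, adjusted p = 0.0274) and the scavenger receptor Cd36 from 163 ± 68.8 to 41.3 ± 16.9 (-1.72 ± 0.34, adjusted p = 0.0480). The list of lipid and lysosome genes did not pass here, with 5 of 15 higher (median log2 -0.18, camera adjusted p = 0.431), 2 past over all genes and 3 adjusted over the list alone.

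Also lower in knock-out monocyte-like cells were the cystine transporter Slc7a11 (log2 fold -1.94 ± 0.31), metallothionein Mt1 (-1.23 ± 0.20, both adjusted p = 0.0236), Rpl29 (-0.82 ± 0.14, adjusted p = 0.0267). So were Mtss1 (-1.39 ± 0.26), Gm42031 (-4.54 ± 0.69, both adjusted p = 0.0274), coagulation factor F10 (-0.80 ± 0.17, adjusted p = 0.0467), Ckap4 (-0.84 ± 0.18, adjusted p = 0.0480), the glutamine transporter Slc1a5 (-1.37 ± 0.30, adjusted p = 0.0482) and Mdm2 (-0.84 ± 0.18, adjusted p = 0.0499). The edgeR test held 5427 genes in 5 wild-type and 4 knock-out animals, 841 with an unadjusted p under 0.05, and DESeq2 called 99, 40 of them shared. The genotypes held different monocyte clusters. The one led by Ccl12, Cxcl10 and Ifit2 took 28.2% of knock-out and 8.10% of wild-type monocyte-like cells. The one led by Cxcl1, Mmp19 and Vcan took 6.10% and 29.8%. These shares are pooled over cells and rest on few animals: of the first cluster, wild-type animal 1 gave 36 of 54 wild-type cells and knock-out animals 1 and 5 gave 111 and 114 of 245, and of the second wild-type animal 5 gave 93 of 199. Leaving out single wild-type animals 1 to 5 gave 246, 19, 1, 0 and 3 genes. Leaving out knock-out animals 1, 2, 4 and 5 gave 6, 96, 1 and 3. The coarser clustering gave 0, well 1 gave 14 and well 2 gave 72. Cd74, Rilpl1, Psme1, Mtss1, Fam111a, H2-T23 and Tapbp overlap other genes, and MHC, Gbp and Mt genes have near-identical relatives, so their counts are less certain.

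As lists, 12 of 12 MHC class I genes (median log2 0.88, camera adjusted p = 2.08e-08, adjusted p = 0.749 with an estimated correlation) and 19 of 19 type I interferon response genes (median 1.14, camera adjusted p = 4.97e-08, adjusted p = 0.943 with an estimated correlation) were higher in knock-out monocyte-like cells. Over all genes 3 of the class I genes passed, and 12 adjusted over the list alone. For the interferon genes these counts were 0 by edgeR and 9, with Oas2 at 1.02, Oas1a at 0.92 and Ifit3b at 1.75 (adjusted p from 0.0784 to 0.108). Of 10 MHC class II genes, 9 were higher (median 1.21, camera adjusted p = 2.56e-06, adjusted p = 0.674 with an estimated correlation), 4 of them past over all genes and 7 adjusted over the list alone. So were 5 of 5 genes of the interferon-gamma program (median 1.22, camera adjusted p = 0.000802, adjusted p = 0.749 with an estimated correlation), 1 past over all genes and 4 adjusted over the list alone, with Irf1 at 0.84. All 12 mitochondrially encoded genes were lower (median -0.23, camera adjusted p = 0.000738, adjusted p = 0.950 with an estimated correlation). Of them, 0 passed over all genes and 7 adjusted over the list alone, for example mt-Nd5 (-0.55), mt-Nd4 (-0.44) and mt-Cytb (-0.36). Of 18 NF-kB targets and inflammatory cytokines, 6 were higher (median -0.22, camera adjusted p = 0.0238, adjusted p = 0.996 with an estimated correlation). The leading ones were Tnf at -0.98, Cxcl1 at -1.56 and Nfkbia at -0.49, with 0 past over all genes and 0 adjusted over the list alone.

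**Figure D3:**
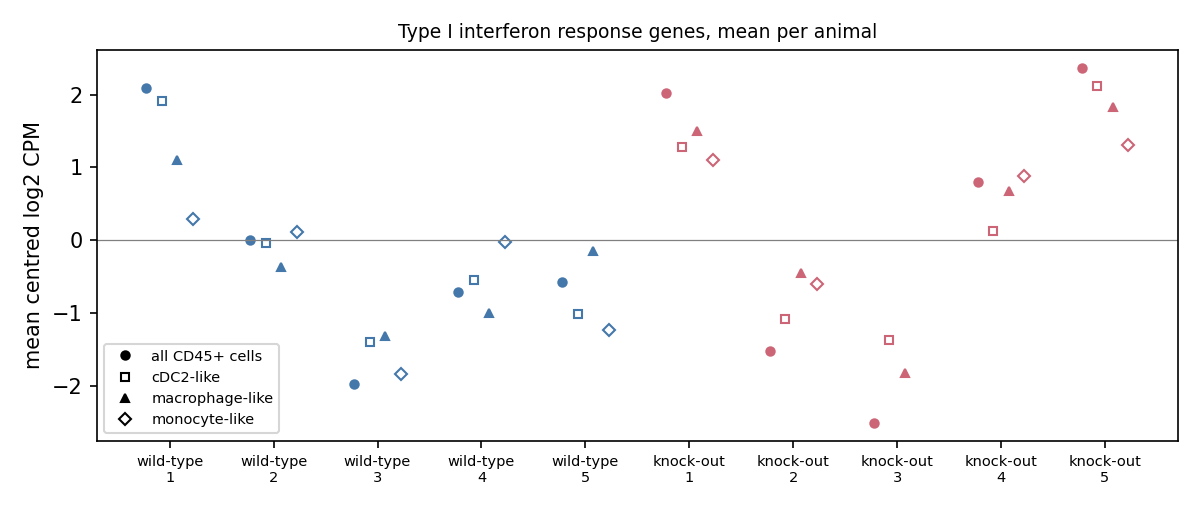
Mean centred log2 CPM of the type I interferon response list per animal, in all CD45+ cells and in cDC2-like, macrophage-like and monocyte-like cells, by genotype; each point is 1 animal. Animals of both genotypes lie at either end outside monocyte-like cells, for example wild-type animal 1 at 2.09 and knock-out animal 3 at -2.51 over all CD45+ cells.

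Over the 7 classes, 17 of 104 pairs of list and class passed camera with the preset correlation. With an estimated correlation 0 passed, and with fry 0 for a shared direction and 1 for change in either direction (MHC class II in monocyte-like cells, adjusted p = 0.0116). STAT3 target genes, downstream of the IL-20 receptors in epithelium, passed in none of the 7 classes by camera (adjusted p from 0.467 to 0.996). The dissociation response did not pass in these 7 either, nor did genes of the response to IL-4 and IL-13 in the 5 classes with enough measured members. The type I interferon list in cDC2-like cells had 16 of 16 members higher (median log2 0.48, camera adjusted p = 0.192).

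The genotype effect itself differed between classes for some genes. Between ILC2-like and monocyte-like cells, 14 of 3888 genes differed by edgeR (7 in each direction). Among them were the nuclear lamina gene Lmna (log2 difference 1.82 ± 0.26, adjusted p = 0.000117, with 0.68 in ILC2-like and -1.20 in monocyte-like cells), Txnip (-1.82 ± 0.32, adjusted p = 0.00122, with -1.24 and 0.51) and Vim (0.94 ± 0.18, adjusted p = 0.00234, with 0.28 and -0.72). Ptafr differed between ILC2-like and cDC2-like cells (-1.73 ± 0.36, adjusted p = 0.0149), the 1 gene of 5900. Between T-like and monocyte-like cells (5 wild-type and 3 knock-out animals) 5 genes differed, led by the interferon-gamma-induced transcript AW112010 (-2.20 ± 0.37, adjusted p = 0.00540). Between T-like and cDC2-like cells 5 differed, led by the nuclear RNA Malat1 (-0.73 ± 0.13, adjusted p = 7.77e-05).

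These counts moved with single animals. For ILC2-like against monocyte-like cells they were 8, 6, 9, 27, 5 and 8 without wild-type animals 3 and 5 and knock-out animals 1, 2, 4 and 5. Against cDC2-like cells they were 3 and 0 without wild-type animals 1 and 3, 2 without wild-type animal 4 or 5 or knock-out animal 1 or 5, and 0 without knock-out animal 2. T-like against monocyte-like cells gave 9, 0, 0 and 1 without wild-type animals 1, 3, 4 and 5 and 2, 39 and 1 without knock-out animals 1, 2 and 5. T-like against cDC2-like cells gave 11 and 2 without wild-type animals 3 and 4 and 11 and 15 without knock-out animals 2 and 3.

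Rpl29 and Nudt16 lie on chromosome 9, as does Il20rb, at 5.97 and 4.67 Mb from it. Within 10 Mb of Il20rb, 8 of 112 tested genes had an unadjusted p under 0.01 by edgeR over all CD45+ cells, against 176 of 9770 elsewhere. Because this window was chosen after the values of Rpl29 were seen, Rpl29 and Nudt16 were left out of the test, which leaves 6 of 110 genes (odds ratio 3.14, 95% interval 1.11 to 7.22, Fisher exact p = 0.0159). Fisher's test takes genes as independent, but Dusp7, Abhd14a and Abhd14b lie beside Rpl29, at 5.91, 5.98 and 5.99 Mb from Il20rb. The interval may thus be too narrow and the p too small.

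**Figure D4:**
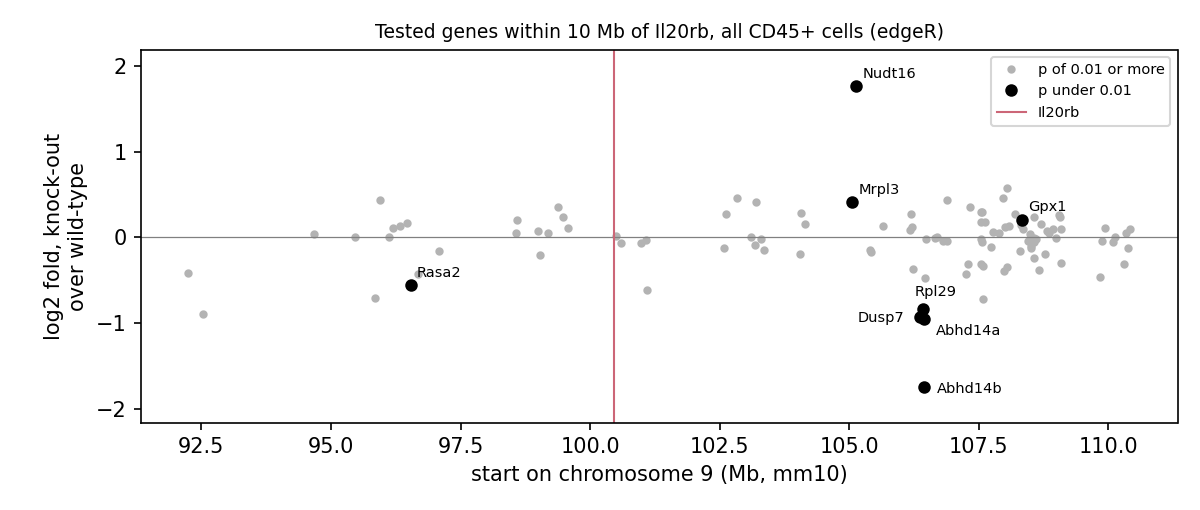
Log2 fold (knock-out over wild type, all CD45+ cells) of the 112 tested genes within 10 Mb of Il20rb against their start on chromosome 9; each point is 1 gene and those with an unadjusted p under 0.01 are named. Rpl29 (-0.83) and Nudt16 (1.77) had the lowest p values.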

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

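The rule for a far animal and the test of a genotype effect that differs between classes were set in advance; the tests of other splits of the animals, and the tests between classes without each animal in turn, were chosen after the results were seen. Of 159 groups of animals checked, 24 held an animal far from the others of its genotype (15.1%). The rule flags about 1 in 20 groups by chance only where values are normally distributed, which sparse counts and shares are not. A group where only 1 animal gave any UMI or cell is flagged by construction, as for Il20ra and plasma-like cells in wild-type animals. The 15.1% therefore cannot show an excess of far animals over chance. Most of the 24 rest on rare cells or low counts, and no biological explanation was tested.

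Shares of cells stood apart in single animals. Wild-type animal 3 held 7.91% B-like cells (0.6% to 1.10% in the others), 2.10% plasma-like cells (0% in the others) and 0.494% fibroblast-like cells (0% to 0.112%). Wild-type animal 1 held 4.68% macrophage-like cells (16.6% to 21.4%). Knock-out animal 5 held 1.62% NK-like or ILC1-like cells (0% to 0.369%), knock-out animal 4 held 0.240% fibroblast-like cells (0% in the others) and knock-out animal 1 held 0.114% plasma-like cells (0% in the others).

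Cytokine and receptor genes over all cells did so too. Il4 reached 94.2 CPM in wild-type animal 2 (0.347 to 4.50 in the others) and 50.6 in knock-out animal 1 (0 to 1.20), and Il13 reached 37.4 in wild-type animal 2 (0.693 to 7.88). Il5 stood at 6.82 in knock-out animal 2 (1.11 to 2.10). Il20ra gave 0.308 CPM in wild-type animal 4 and Il19 gave 0.558 in wild-type animal 2, each 0 in the other wild-type animals. Of eosinophil genes, Il5ra (5.28, others 0 to 0.438) and Prg2 (9.78, others 0 to 0.219) were highest in wild-type animal 3, Siglecf stood at 2.47 in knock-out animal 1 (1.60 to 1.68) and Il5ra at 0.401 in knock-out animal 2 (0 in the others). Wild-type animal 3 also held the largest shares of B-like and plasma-like cells. Which cells carried the UMIs was not tested, so these values do not show eosinophils in that animal. Xist, the RNA of the inactive X chromosome, stood at 416 CPM in wild-type animal 1 (656 to 743).

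Among genes that passed a test, Ptafr in ILC2-like cells stood at 209 CPM in knock-out animal 4 (71.1 to 90.8 in the others). In monocyte-like cells Ifi208 stood at 30.2 in wild-type animal 2 (0 to 6.37), Mapk9 at 4.86 in wild-type animal 4 (9.63 to 10.8) and F10 at 190 in wild-type animal 1 (255 to 280). In knock-out animal 2, Rilpl1 stood at 0 (47.0 to 51.0) and Lpl at 146 (62.4 to 75.6).

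The genotype effect differed between ILC2-like and monocyte-like cells, by the edgeR interaction test, for 14 genes. It was higher in ILC2-like cells for Hmgcs1, a sterol synthesis enzyme (log2 difference 2.56, adjusted p = 0.0064), Lmna (1.82), Rgcc (1.67), Malt1 (1.63), Anxa2 (1.00), Vim (0.94) and S100a10 (0.70). It was lower for Il2ra, the IL-2 receptor alpha chain (-3.09, adjusted p = 0.0398), with 2 and 22 UMIs in wild-type and knock-out monocyte-like cells, and for Cd74 (-1.96), Txnip (-1.82), Ptafr (-1.66), the activation marker Cd69 (-1.46), Clec2d (-1.38) and Ly6e (-0.81). In wild-type and knock-out ILC2-like cells, Cd74 gave 67 and 13 UMIs and Hmgcs1 gave 33 and 34, and neither was tested in that class alone. Of 126 possible splits 60 were run, and 1 of them, the real one, gave as many as 14 genes, the highest of the others giving 13. This does not exclude chance for the count of 14, since the remaining splits were not run. The count also ranged from 5 to 27 without single animals.

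Ptafr also differed between ILC2-like and cDC2-like cells (-1.73), a count of 1 gene for which chance could not be excluded (30 of 60 splits gave as many, the highest 21, which points to a structure of the samples). Between T-like and monocyte-like cells the effect was lower in T-like cells for the creatine kinase Ckb (-9.00), AW112010 (-2.20), H2-D1 (-0.87), Tmsb10 (-0.76) and Malat1 (-0.65). For Ckb, T-like cells gave 47 UMIs in wild-type animals and 4 in knock-out animals, all from 1 of 4 knock-out animals. The fit held only 3 of these knock-out animals, so -9.00 rests on at most 4 knock-out UMIs and is no measure of size. In this test 3 of 56 splits gave as many as 5 genes, the highest 13. Between T-like and cDC2-like cells the effect was lower in T-like cells for Capg (-1.47), Lsp1 (-1.18), Zfp36l2 (-1.07), Malat1 (-0.73) and Crip1 (-0.61), and 9 of 60 splits gave as many as 5, the highest 31, which again points to a structure of the samples. Chance could be excluded for neither count.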

How the results depend on the processing

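The settings without the top doublet scores, without monocyte-like and neutrophil-like cells and the interaction tests without single animals were chosen after seeing the data. No paired analysis was possible because the labels pair no animal of 1 genotype with an animal of the other. Counting each named gene once per class, so that Rpl29 counts several times, 48 passed and 4 of those did so in every setting, with 0 reversed. Of 102 that did not pass, 40 did in some setting and 7 reversed in some. Over all settings, class shares were the same in 249 cases and reversed in 19, gene lists the same in 144 and weaker in 60, and named genes the same in 2335, weaker in 331, stronger in 101 and reversed in 27. Filtering cells at 500 genes and 10% mitochondrial UMIs left 6054. Every deposited cell already met these limits, so this setting could change nothing and checks nothing. The share of cells with Il20rb differed between genotypes by -0.0469 points with or without it. Alternatives that need hashtag counts, a replicate block and the removal of called doublets were not run, and wells alone could not be fitted for ILC2-like, T-like, cDC1-like and cycling cells, nor 20 cells per animal for ILC2-like, T-like and cycling cells, for lack of animals. Depth limits the lymphoid classes most, with 1008 genes testable in T-like cells. For the changes below the cause was not tested, except that leaving out animals leaves fewer samples and dropping the filter tests more genes.

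Without monocyte-like and neutrophil-like cells in the denominator 3 classes passed, with ILC2-like at -6.44 and T-like at -4.32 points, and macrophage-like cells reversed to 0.544; they also reversed with immune classes only (0.765), doubled resolution (1.02) and well 1 (1.83). Langerhans-like cells reversed with doubled resolution (-0.00877), cDC1-like cells in well 1 (-0.350) and basophil-like cells without the top doublet scores (9.76e-05). Without single animals the share difference ranged from -1.76 to 0.288 for cycling, -2.96 to 1.21 for macrophage-like, -0.121 to 0.0202 for fibroblast-like and -0.503 to 0.0228 for plasma-like cells.

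DESeq2 called 74 genes in all CD45+ cells, 3 in T-like, 1 in cDC1-like, 8 in cDC2-like and 99 in monocyte-like cells. With no filter on low counts there were 7 in all CD45+, 12 in ILC2-like, 14 in T-like, 12 in cDC1-like, 32 in cDC2-like, 10 in cycling, 34 in macrophage-like and 354 in monocyte-like cells. Library totals gave 2 in T-like and 4 in cDC2-like cells, and no robust dispersion gave 0 in cDC1-like cells by edgeR, where 110 had an unadjusted p under 0.05 in the chosen fit. Well 1 gave 2 in all CD45+, 0 in macrophage-like (edgeR; 253 at an unadjusted p under 0.05 with both wells, 4 by DESeq2) and 14 in monocyte-like cells, and well 2 gave 1 in cDC2-like, 0 in macrophage-like and 72 in monocyte-like cells. At least 20 cells per animal gave 0 in cDC1-like and 96 in monocyte-like cells. Halved resolution gave 2 in cDC1-like, 6 in cDC2-like and 0 in monocyte-like cells (edgeR; 841 at an unadjusted p under 0.05 at the chosen resolution), doubled resolution 2, 4 and 27. Without the top doublet scores there were 1 in cDC1-like, 6 in cDC2-like and 76 in monocyte-like cells, and without monocyte-like and neutrophil-like cells 43 in all CD45+ cells. Of the lists, 0 passed with an estimated correlation, 0 with fry and 1 with fry for either direction.

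Without single animals the calls ranged from 1 to 5 in all CD45+ cells, 2 to 10 in ILC2-like, 0 to 2 in T-like, 0 to 2 in cDC1-like, 1 to 6 in cDC2-like, 1 to 2 in cycling, 1 to 6 in macrophage-like and 0 to 246 in monocyte-like cells. For the interaction they ranged from 5 to 27 (ILC2-like against monocyte-like), 0 to 3 (ILC2-like against cDC2-like), 0 to 39 (T-like against monocyte-like) and 2 to 15 (T-like against cDC2-like).

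Il10rb and Il1rl1 passed nowhere and reversed in several settings. The reversed values were 0.12 at halved resolution (Il10rb, cycling cells), then -4e-04 with library totals, -0.0131 in well 1, -0.137 at halved and -0.0909 at doubled resolution and -0.0219 without the top doublet scores (Il10rb, macrophage-like cells). They were 0.18 with DESeq2 and 0.0817 at halved resolution (Il1rl1, macrophage-like cells). Without single animals the ranges were -0.28 to 0.24 (Il10rb, all CD45+ cells), -0.53 to 0.17 (Il10rb, cycling cells), -0.0742 to 0.18 (Il10rb, macrophage-like cells) and -0.0944 to 0.22 (Il10rb, monocyte-like cells). They were -0.46 to 0.0112 (Il1rl1, all CD45+ cells), -0.0692 to 0.54 (Il1rl1, cDC2-like cells) and -0.31 to 0.50 (Il1rl1, macrophage-like cells).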

Other observations

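Chosen only after the result was seen were the fit without monocyte-like and neutrophil-like cells and the tests below of the chromosome 9 window, of Rpl29 by class, of glucocorticoid exposure, of the dissociation response, of the monocyte clusters, of single animals and of other splits; the tests of Il7r and of the glucocorticoid genes against the class mix were written first.

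Without monocyte-like and neutrophil-like cells, 43 genes differed over the remaining cells, 13 higher and 30 lower in knock-out animals, all 4 of the genes called in all CD45+ cells among them (edgeR, n = 5 per genotype). In these cells the share of ILC2-like cells fell from 10.4 ± 3.25% to 3.91 ± 1.03% and that of T-like cells from 7.74 ± 1.98% to 3.42 ± 1.22% (exact permutation p = 0.00794 for each). Among the lower genes were Ltb, which encodes lymphotoxin beta (log2 fold -1.49, adjusted p = 0.0187), the transcription factor Ikzf3 (-1.36, adjusted p = 0.0309), the adaptors Skap1 (-1.03, adjusted p = 0.0261) and Lat (-1.13, adjusted p = 0.0490), the receptors Klrg1 (-1.41, adjusted p = 0.0467) and Cxcr6 (-1.70, adjusted p = 0.0483), Kit (-1.18, adjusted p = 0.0491) and Il7r (-0.86, adjusted p = 0.0278). In the same cells Nudt16 (1.77, adjusted p = 0.000847), the extracellular superoxide dismutase Sod3 (1.82, adjusted p = 0.00210) and Acvrl1 (0.70, adjusted p = 0.0298) were higher, and the protease inhibitor Serpinb1a (-1.04, adjusted p = 0.0122) and the noncoding G530011O06Rik (-6.66, adjusted p = 0.000847) were lower.

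Rpl29 and other genes near Il20rb on chromosome 9 differed between the genotypes. A different mix of cell classes is excluded as the cause for Rpl29, since within the class where its difference was smallest it was still -0.67 log2. A candidate explanation is a chromosome 9 segment carried over with the knock-out allele from another strain: with Rpl29 and Nudt16 left out, 6 of 110 genes within 10 Mb of Il20rb (Dusp7, Mrpl3, Gpx1, Rasa2, Abhd14a and Abhd14b) had an unadjusted p under 0.01, against 176 of 9770 elsewhere (odds ratio 3.14, 95% interval 1.11 to 7.22, Fisher exact p = 0.0159). Dusp7, Abhd14a and Abhd14b lie beside Rpl29, so the genes are not independent as Fisher's test takes them, and its p may be too small. Within classes, with fewer genes tested, the odds ratio was 4.34 in macrophage-like, 3.63 in cDC1-like, 1.63 in monocyte-like, 1.32 in cDC2-like and 0 in ILC2-like, T-like and cycling cells, and each of these 95% intervals included 1. An effect of the receptor on these genes, and reads that a strain variant or a copy of Rpl29 moves, were not tested and stay open.

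Of the genes lower in knock-out animals, Tsc22d3, Ddit4, Txnip and Mt1, each past the threshold in 1 class, are known to be raised by glucocorticoids, as are Fkbp5, Zfp36l2 and Cxcr4, which passed in none, and Il7r. They were picked because they were low, and Txnip stood at 0.51 in monocyte-like cells, so the pattern is a hypothesis. As a set, the 7 genes other than Il7r are not explained by the mix of broad classes alone, which predicts a median log2 difference of -0.08 against -0.94 observed. The observed median is itself lowered by the picking, with single genes from -1.41 (Fkbp5) to -0.189 (Mt1). Clusters within classes were not modelled. For Txnip the class mix predicts -0.249 of -0.341 and for Il7r -0.54 of -0.80. Over all CD45+ cells the mix cannot be told apart from a change within cells for either gene. Within ILC2-like cells, where the class mix plays no part, Txnip fell by 1.24 log2 (edgeR adjusted p = 0.0404). A weaker response to dissociation in the knock-out cells was not seen in the immediate early genes. Their medians ran from -0.107 in monocyte-like to 0.159 in macrophage-like cells. In 8 of 8 sets of cells they lay above the noticed genes by more than the spread of their members. That gap cannot exclude this cause, because the noticed genes were picked for being low and the sets overlap. Lower glucocorticoid exposure of the knock-out animals may account for the pattern but cannot be told apart from other causes: responsive genes not looked at before reached a camera p under 0.05 in 0 of 3 myeloid classes (medians 0.02 in cDC2-like, -0.09 in macrophage-like and -0.22 in monocyte-like cells), and had a median of -0.25 over all CD45+ cells (camera p = 0.0211, p = 0.154 with an estimated correlation).

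As lists, by camera with the preset correlation alone, interferon and antigen-presentation genes were higher in knock-out monocyte-like cells. An inflammatory state of single animals of both genotypes may account for part of it, but the ranks cannot decide this. In 3 of 3 sets of cells, all CD45+, cDC2-like and macrophage-like, a wild-type animal ranked among the 3 highest for the type I interferon list. A knock-out animal ranked among the 3 lowest in each. Most random rankings of 5 against 5 animals would do the same, and the sets hold the same animals. The list did not separate the genotypes in these sets (exact permutation p = 0.698, 0.635 and 0.405). Over all CD45+ cells, however, the low knock-out animals 2 and 3 (-1.52 and -2.51) held 4.10% and 2.58% monocyte-like cells. In monocyte-like cells themselves knock-out animals 5, 1 and 4 ranked 1, 2 and 3 of 9 for the list and knock-out animal 2 ranked 7, while for Ifi208, Gbp5, Gbp7, Cd74, H2-Ab1, H2-T23, Tapbp and Psme1, named because they passed, the genotypes did not overlap, and for Cd40, which also passed, they did. The monocyte clusters that each genotype holds cannot be told apart from a change within cells: both lists were also higher in macrophage-like cells (lower median 0.52), but the mix of macrophage clusters was not tested, and with an estimated correlation the interferon list there had p = 0.269 and the class I list p = 0.0346. An effect of the genotype stays open and untested.

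Other splits of the animals were counted for each fit. Few of the 100 splits run, of 126 possible, gave as many calls as the 4 genes over all CD45+ cells (3 of 100, the highest other 909). The same held for 7 in ILC2-like cells (1 of 100, the highest other 3). It also held for 2 in cDC2-like cells (2 of 100, the highest other 102) and 42 in monocyte-like cells (2 of 100, the highest other 218). These shares do not exclude chance: they were not adjusted over the fits, and the test was chosen after the results were seen. The 42 calls also fell to 0 without wild-type animal 4. More splits gave as many for 4 in cDC1-like cells (5 of 100, the highest other 24) and 3 in macrophage-like cells (7 of 100, the highest other 77). So they did for the 17 lists (25 of 100, the highest other 33), and chance could not be excluded there either. With 0 genes called in T-like cells (edgeR, with 83 at an unadjusted p under 0.05 and 3 by DESeq2), all 100 splits give as many by construction (the highest other 3), which tests nothing. For the 2 genes in cycling cells the 10 splits are too few, with the highest other at 6 and 4 splits giving as many. The split with 909 genes set wild-type animals 1 and 2 with knock-out animals 1, 4 and 5 against the rest. Those with 102, 77 and 218 genes likewise point to a structure of the samples other than genotype. The split with 218 genes set wild-type animals 3, 4 and 5 with knock-out animal 2 against the rest. It overlapped genotype in part, since knock-out animals 1, 4 and 5 lay on the same side.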
